A study of Drosophila melanogaster with 4 samples.

How the data were processed

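Whole-animal total RNA of 4 baseline samples of Drosophila melanogaster was measured, 1 sample per array, on one-colour Affymetrix Drosophila arrays. The deposited values are intensities on a linear scale, 1 per probe set and sample, which the authors normalized between arrays with DNA-Chip Analyzer (dChip) through probes selected as invariant, per the labels. The dChip version, its background model, the set of arrays normalized together and any detection calls are not given in the sources used here. No value lay at or below 0, and the 4 columns had nearly equal medians, so no further normalization was applied. An invariant-set normalization assumes that most probe sets do not change and can leave or introduce differences that depend on intensity. Depth has no direct measure on arrays; the precision is limited by the number of arrays, 4.

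The table held 14010 probe sets. The 44 Affymetrix control probe sets were kept out of all tests and summarised separately. Values below the 20th percentile of all values (57.1) were raised to it, log2 was taken, and the 8379 probe sets whose mean log2 value exceeded the 40th percentile of means were tested. Of the 13966 probe sets that are not controls, 12443 matched 1 gene, 327 several genes and 1196 none in the platform annotation. Genes were named only from probe sets with 1 gene, except where the text says that a probe set matches several. Symbols of 12394 probe sets were updated through their gene identifiers to NCBI RefSeq's table for the Release 6 plus ISO1 MT assembly of the fly genome. No coordinates were used. Where a gene had several probe sets, the list tests used the one with the highest mean; levels of different probe sets were not compared with each other, except for the 3' to 5' ratio of control transcripts, which was compared between libraries only.

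Analyses were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The group has no contrast group, so 4 kinds of question were set before the data were examined. Agreement was described by pairwise correlations and log2 differences. Variable genes were sought by a limma-based test: the variance of each probe set over the 4 libraries against the prior variance of probe sets of like intensity (squeezeVar, robust, with an intensity trend), upper tail of an F distribution with a prior of 7.26 degrees of freedom. A trend over the labelled hour, and each library against the mean of the other 3, were tested in limma with a robust, trended prior, two-sided. In the last test the lone library is assumed to vary like the others. Benjamini-Hochberg adjustment was applied within each test, with a threshold of 0.05.

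A total of 25 gene lists were fixed before the data were examined, by symbol or family name: egg shell and yolk, germline and oogenesis, male accessory gland and ejaculatory duct, testis, antimicrobial and immune, Turandot stress, heat shock, digestive serine proteases, carbohydrate digestion, lipid metabolism, glycolysis and gluconeogenesis, oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis, insulin and TOR signalling, circadian clock, cuticle, muscle structure, photoreceptor, odorant-binding proteins, neuronal, cytochrome P450, glutathione S-transferase, cell cycle and DNA replication, and larval and pupal residue. Of their members, 2 were not matched to a gene. The 24 lists with at least 4 tested members were compared with 10000 random lists matched on intensity in 20 bins, once for the spread between libraries of the list's median deviation and once for the members' SD relative to the SD expected at their intensity. The share of random lists with as large a value describes these 4 libraries, since genes are not replicates; the smallest share possible is 0.0001. Slopes over the labelled hour were tested per list with limma's camera, with a preset correlation of 0.01 and, beside it, an estimated one. With 4 libraries, camera has few degrees of freedom once the correlation is estimated, so that setting can hardly call a list.

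Genes named in the text follow a rule also set beforehand: the 20 genes with the smallest p for variability, the 5 rising and 5 falling genes with the smallest p over the labelled hour, the 3 higher and 3 lower genes with the smallest p for each library, in each list the member with the largest and the one with the median ratio of SD to expected SD, with up to 2 more where the list passed a test, and 18 genes of insulin signalling, the clock and yolk named whatever their values. Genes outside the rule are members of small counts, or were chosen after their values were seen. The text gives them with that reason or with the count.

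Alternative settings were a floor at the 5th percentile, an offset of 57.1 in place of the floor, no filter, a filter at the 60th percentile, quantile normalization, median centring, each replicate left out in turn, a prior variance that is not robust or has no trend, the first against the last 2 labelled hours, the mean of list members, all probe sets of a gene averaged, and the estimated correlation. No floor and no filter together, the male lists limited to members that pass the filter on the other 3 libraries, and the other orders of the 4 libraries, were added after seeing the data.

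The tests were checked on simulated data for 8379 probe sets with known changes. In the variability test, a shift of 1 library by 0.5 log2 units was recovered for 0% of 67 changed probe sets, by 1 unit for 92.5% and by 2 units for 100%. The test of 1 library against the others recovered 64.2% of shifts of 0.5 and 100% of the larger ones. For the labelled hour, slopes of 0.1, 0.2 and 0.4 were recovered for 2.99%, 58.2% and 97.0%. With unchanged data the 3 tests made 0, 0 and 1 false calls, the last for the labelled hour, and beside the simulated changes they made 2, 10 and 7. Of the lists, 0 were called in unchanged data, 1 where 1 list was shifted in a library, and 2 over the labelled hour where 1 list had been given a slope. Simulated probe sets varied independently of each other, so these list counts do not measure false calls where genes of a list move together. Their values were drawn from the spread that the tests assume, equal in each library and without a shift shared by some libraries. Recovery and false calls for single probe sets may therefore differ in the measured data.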

Results

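RNA from whole adult Drosophila melanogaster was measured on 4 one-colour oligonucleotide arrays, each with the RNA of 1 baseline sample, so that the data hold a single group with n = 4. Per the labels, the animals fed normally as young larvae, were moved early in the third larval instar to food without yeast, the protein source of the standard diet, and stayed on that food until 4 days after they emerged as adults. The baseline flies were killed immediately before a refeeding time course and therefore stand for the yeast-deprived state at its start. The labels place the samples, here called libraries 1, 2, 3 and 4, in the order of hours -4, -3, -2 and -1 for a change-point analysis, without saying that the flies were killed at those hours. The sex of the flies, the number of flies per sample and the number of separate cultures are not given in the sources used here. No p-value below therefore speaks for flies beyond these 4 samples. The shares and the camera p-values with a preset correlation rest on genes, which are not replicates. Refed flies and later time points are not analysed here. After 44 control probe sets were set aside, 13966 probe sets remained, and 8379 of them, with 6822 named genes, passed the intensity filter and were tested. The median normalized intensity was 112 in library 1, 112 in library 2, 113 in library 3 and 112 in library 4.

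The first question was how closely the baseline samples agreed, since this spread is the error against which a later time point would be read. Most genes had nearly the same level in the 4 libraries, among them the core genes of insulin signalling. The insulin-like peptide gene Ilp2 had an intensity of 142 ± 1.67 (SD, n = 4), and chico, which encodes the insulin receptor substrate, one of 335 ± 4.82 (SD, n = 4). Ilp2, like the clock gene per below, lay close to the highest single negative control, which had 119 to 133 over the libraries. The spread of Ilp2 and per therefore says little about their expression. The intensity was 189 ± 10.6 for the insulin receptor gene InR, 175 ± 6.81 for the kinase gene Akt, 218 ± 15.4 for the transcription factor gene foxo and 883 ± 66.3 for ImpL2, whose product binds insulin-like peptides (SD, n = 4). S6k, a kinase gene of the TOR pathway, had a wider spread at 320 ± 40.4, with 345 and 363 in libraries 1 and 2 against 283 and 288 in libraries 3 and 4. Thor, Ilp3 and Ilp5 were not among the named probe sets and were not analysed here. The clock genes gave 156 ± 9.51 for per, 540 ± 47.2 for tim, 206 ± 19.6 for cry and 242 ± 7.48 for vri, while Clk, at 57.9 ± 5.25, lay below the filter (SD, n = 4). The yolk protein genes Yp1, Yp2 and Yp3 had intensities of 224 ± 35, 227 ± 29.1 and 334 ± 40.6 (SD, n = 4). None of these genes passed the test for excess variability described below.

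Over all tested probe sets the median coefficient of variation was 5.24%, the median SD of log2 intensity was 0.08, and 95% of probe sets had an SD of 0.18 or less. The median absolute log2 difference between 2 libraries was 0.09 over the 6 pairs. Pearson correlations across probe sets, which are not independent replicates, ran from r = 0.982 for libraries 2 and 3 to r = 0.994 for libraries 1 and 2, and Spearman correlations of the same pairs from rho = 0.964 to rho = 0.986. Between libraries 1 and 3, the pair with the most such differences, 0.274% of probe sets differed by more than 2-fold, and between libraries 1 and 4 the share was 0%. No pair of libraries held identical values.

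Control probe sets separated libraries 3 and 4 from libraries 1 and 2. The 9 probe sets for bacterial hybridisation controls, added in fixed amounts, were on average brighter than in library 1 by a factor of 1.59 in library 3 and 1.29 in library 4, and stood at 0.927 times library 1 in library 2. The log2 ratio of the 3' to the 5' probe set, averaged over actin, GAPDH and eIF-4a control transcripts, was 1.14 in library 1 and 1.05 in library 2 against 1.44 in library 3 and 1.40 in library 4. Among 23 probe sets for mouse, yeast and unused bacterial sequences, the median intensity lay between 46.1 and 48.7 in each library, and single probe sets reached 133. Values of genes near or below that level therefore carry little information on abundance.

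**Figure D1:**
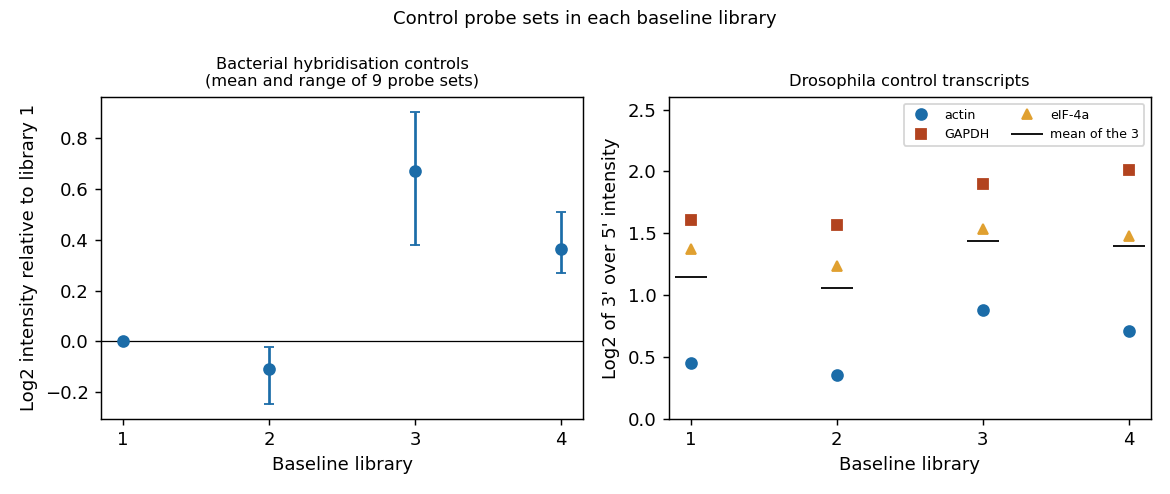
Control probe sets in the 4 baseline libraries. Left, log2 intensity of 9 hybridisation controls relative to library 1 (point, mean; bar, range over probe sets), with means of 0.67 in library 3 and 0.36 in library 4. Right, log2 ratio of 3' to 5' probe set intensity for 3 control transcripts (symbols) and their mean (horizontal line), which was 1.44 in library 3 and 1.05 in library 2.

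The most variable genes were male reproductive genes, and their variation came from library 3. Mst57Da, a male accessory gland gene, had an intensity of 662 in library 3 and of 69.0 to 74.5 in the other libraries. Acp95EF, another accessory gland gene, had 416 in library 3 and 41.5 to 45.8 elsewhere. The male-specific testis transcripts Mst84Dd, Mst87F and Mst84Da were variable too, with 478, 380 and 473 in library 3 against 126 to 133, 92.7 to 119 and 187 to 192. Their SD of log2 intensity exceeded that expected at their intensity 19.4-fold for Mst57Da, 12.2-fold for Mst84Dd, 12-fold for Mst87F and 8.12-fold for Mst84Da, with adjusted p from 7.03e-05 to 0.00881 in the limma-based test. Acp95EF passed as well (adjusted p = 0.000101), but its values outside library 3 lay below the floor of 57.1 and no higher than the median negative control, so the floor sets the size of its SD. Of the 23 variable probe sets described next, 8 had a mean below the filter without library 3 and were tested only because of it, among them Mst57Da, Acp95EF, CG12699 and CG1394.

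In all, 23 probe sets had a larger variance than probe sets of like intensity at an adjusted p under 0.05, and 17 of them named 1 gene. Library 3 was the farthest from the median for 20 of the 23, higher in 19, and library 2 for the remaining 3. Of the 23, 6 belonged to the accessory gland and testis lists. Without library 3, 0 probe sets passed (limma-based test; 429 had an unadjusted p under 0.05), against 57, 40 and 45 without library 1, 2 and 4. Besides the male genes named above, further named genes past the threshold had their peak in library 3. Among them was Anp, which encodes an antibacterial peptide of the male tract (295 against 107 to 129). S-Lap7, a leucyl aminopeptidase gene of the testis list, was another (198 against 89.5 to 103). The rest were the small heat shock gene Hsp26 (286 against 135 to 149), CG12699 (190 against 69.0 to 81.5) and CG4836 (316 against 126 to 142), together with CG2127 (287 against 128 to 135), CR17567 (252 against 110 to 126) and CG1394 (175 against 85.7 to 90.1). CG14125 was lowest in library 3, at 143 against 219 to 349. Library 2 was the lowest for CG14642 (133 against 285 to 324) and scaf6 (68.8 against 132 to 156), and the highest for mRpL33, a mitochondrial ribosomal protein gene (299 against 145 to 215). CG15219, CG2246 and klar, next in order of p, missed the threshold with adjusted p of 0.0532, 0.0537 and 0.0547.

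Each library was then set against the mean of the other 3, which shows whether 1 sample stands apart. Library 3 differed at the most probe sets: 47 were higher and 12 lower than in the other libraries at an adjusted p under 0.05 in limma, and 168 and 336 with library 4 left out. With 1 library on one side, the test takes its spread from the other 3 and assumes that library 3 varies like them, so these p-values and SEs do not come from a replicated difference. With library 4 left out, the spread comes only from libraries 1 and 2, the closest pair, which can inflate the counts. Among the higher probe sets that name 1 gene, male reproductive genes led. Mst57Da was higher by a log2 change of 3.20 ± 0.09 (SE, 1 library against 3), and Mst84Dd by 1.89 ± 0.08, with limma adjusted p of 3.24e-08 and 1.22e-06. Outside library 3 Mst57Da lay within the range of single negative controls, which reached 133, and Mst84Dd near its top, so the sizes of these changes carry little information. Of the 47 higher probe sets, 10 had a mean below the filter without library 3. Acp95EF was at least 7.28-fold higher, a lower bound because the other 3 libraries were set to the floor. The genes lower in library 3 with the smallest p were ap, a homeodomain transcription factor gene of wing and nervous system development, by -0.72 ± 0.08, klar, needed for nuclear migration, by -0.89 ± 0.11, and PolH, a DNA polymerase gene, by -0.69 ± 0.09 (limma adjusted p 0.00195, 0.00304 and 0.00622).

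Of 11 tested testis genes, 7 were higher in library 3: Mst84Da, Mst84Db, Mst84Dc, Mst84Dd, Mst87F, S-Lap7 and the testis beta-tubulin gene betaTub85D, with log2 changes from 0.72 to 1.89. The same number, 7, passed when adjusted over the list alone, and the other 4, Mst98Ca, sa, aly and bol, did not pass. Among 5 tested male accessory gland and ejaculatory duct genes, Mst57Da and Acp95EF were higher, and 3 passed when adjusted over the list alone, lectin-46Ca (0.30 ± 0.08) being added. Of the tested genes, Mst57Da, Acp95EF, lectin-46Cb and betaTub85D passed the filter only through library 3. Most members of these lists were too dim to enter the test. Only 30 of the 41 measured members lay above the floor of 57.1 in library 3 itself, so the order of the rest between libraries carries little information. Acp29AB, for example, had 51.74 in library 3 and 51.73 in library 1. On the deposited values without floor or filter, an alternative chosen after seeing the data, all 19 measured accessory gland and duct genes and 16 of 22 testis genes had their highest value in library 3. In that setting 14 and 11 of them passed as higher in limma. Examples picked after their values were seen are EbpII, an ejaculatory bulb gene, at 327 in library 3 against 22.7 to 28.2, and SP, the sex peptide gene, at 165 against 63.8 to 71.3. The 13 tested egg shell and yolk genes showed no such difference as a set, with a median log2 change of -0.05 in library 3. Single members went both ways. Yp1, Yp2, Yp3 and fs(1)N were lower, by -0.36, -0.07, -0.21 and -0.22, and Vm26Aa, Vm34Ca and psd by -0.05 to -0.13. Cp15, Cp16, Cp18, Cp19, Cp36 and yl were higher, by 0.03 to 0.09.

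**Figure D2:**
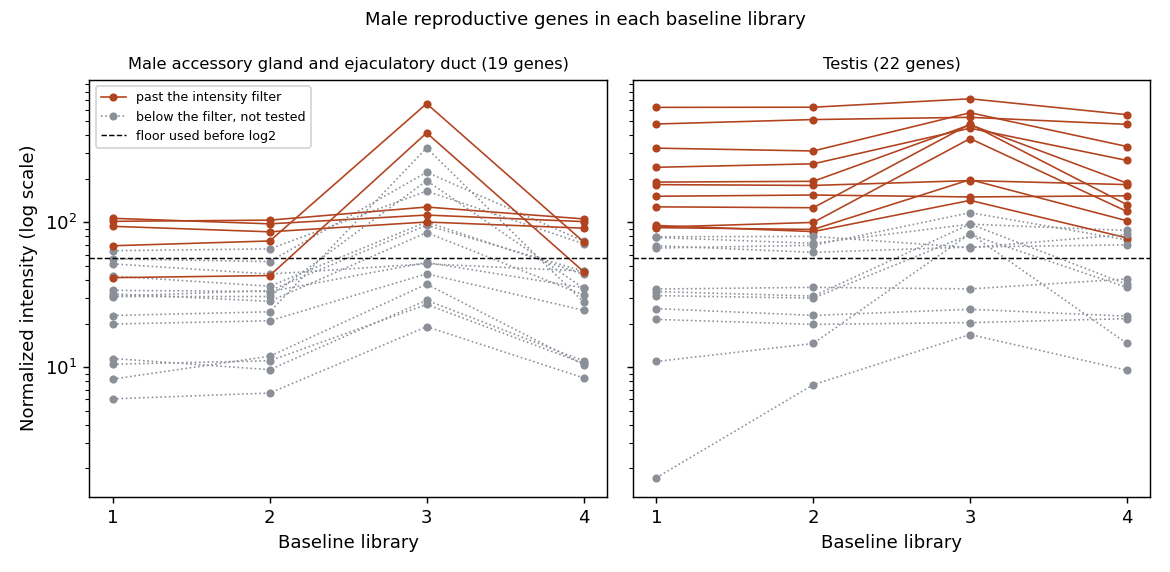
Normalized intensity, on a log axis, of each measured gene of the male accessory gland and ejaculatory duct list (left, 19 genes) and the testis list (right, 22 genes) in the 4 baseline libraries; a line joins the values of 1 gene and implies no order in time, and the dashed line is the floor of 57.1. All 19 genes on the left and 16 of the 22 on the right are highest in library 3, where 30 of the 41 genes shown lie above the floor.

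A few genes of heat shock, digestion and metabolism also differed in library 3, in both directions. Of 7 measured heat shock genes, 6 had their highest deposited value in library 3. Hsp68, below the filter, had 120 there against 43.5 to 49.7. Some probe sets match several Hsp70 genes and so entered no list. Picked after their values were seen, 1 of them had 339 against 89.1 to 93.2. Another, which also matches CG5608, had 199 against 114 to 116. Hsp26 was higher, at 286 against 135 to 149 (limma adjusted p = 0.000261), as 1 of 5 tested heat shock genes. When adjusted over the list alone 3 passed, with Hsp27 (186 against 144 to 167) and the co-chaperone gene stv (229 against 182 to 209) added. Jon74E, a midgut serine protease gene, was higher by 0.83 ± 0.09. It was the 1 of 23 tested digestive protease genes that passed, while 3 passed when adjusted over the list alone, alphaTry (-0.43) and yip7 (-0.31) being lower. In the carbohydrate digestion list the amylase gene Amy-d (-0.70 ± 0.12) and the maltase gene Mal-A1 (-0.58 ± 0.09) were lower, 2 of 13 tested genes and 2 when adjusted over the list alone. FASN1, which encodes fatty acid synthase, was lower by -0.61 ± 0.10 as 1 of 18 lipid metabolism genes, and the lipid droplet gene Lsd-1 (-0.55) was added when adjusted over the list alone, 2 genes in all. Lower as well was RpS19b, 1 of 28 ribosomal protein genes, at -0.54 ± 0.10, and higher was Obp44a, 1 of 19 odorant-binding protein genes, at 0.54 ± 0.09; in each of these lists 1 gene passed when adjusted over the list alone, as did Gpdh1 (lower, -0.38) of the glycolysis and GstS1 (higher, 0.45) of the glutathione S-transferase list.

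Library 2 had 9 differing probe sets in limma, 1 higher and 8 lower. The dynein heavy chain gene Dhc36C was higher at 192 against 109 to 113 (log2 change 0.79 ± 0.09, adjusted p = 0.00615). CG16762 (188 against 132 to 137) and the superoxide dismutase gene Sod3 (451 against 273 to 351), next in order, did not pass, with limma adjusted p of 0.115 and 0.684. CG14642 was lower by -1.18 ± 0.10, CG2246 by -0.94 ± 0.09 and CG7745 by -0.84 ± 0.09 (limma adjusted p 0.00202, 0.00338 and 0.00565). The other 5 lower probe sets named scaf6, Amun, CG17477, sdt and CG14200, with log2 changes from -0.61 to -1.02. Without library 3 the count was 18, and without library 4 it was 5. Cpr72Eb, a cuticle gene, passed when adjusted over the list alone (-0.46).

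Few or no probe sets passed for libraries 1 and 4 under this test. For library 4 this does not mean that it was like the others, since the count depended on the libraries it was set against. In the comparisons below without library 3 or 4, the spread comes only from libraries 1 and 2. These were the closest pair (Pearson r = 0.994), so the counts there can be inflated. In library 1, 0 probe sets passed in limma (172 had an unadjusted p under 0.05). Its nearest candidates were lower for PMP34, a peroxisomal carrier gene (126 against 193 to 204, adjusted p = 0.0536), CG1924 (106 against 154 to 184) and Bdp1 (105 against 132 to 151), and higher for the cytochrome P450 gene Cyp313a3 (251 against 186 to 201), the lipocalin gene GLaz (207 against 156 to 168) and the mucin gene Muc68D (1029 against 701 to 793). In library 4, CG4328 alone passed in limma, lower at 71.3 against 127 to 141 (log2 change -0.89 ± 0.09, adjusted p = 0.0490). The count was 0 under 6 alternative settings of floor, filter, scaling or prior, and with library 1 or 2 left out. CG34458 (373 against 239 to 258), CG7296 (286 against 201 to 208), CG13047 (227 against 166 to 171), unc-13, a synaptic gene (144 against 186 to 194), and CG18130 (102 against 134 to 143) had the next smallest p without passing. When adjusted over the list alone, BomS2 passed in library 1, and lambdaTry and LManVI in library 4. With library 3 left out, however, 503 probe sets differed between library 4 and libraries 1 and 2 in limma, 108 higher and 395 lower. With library 4 left out, library 3 differed from libraries 1 and 2 at 504 probe sets, 168 higher and 336 lower.

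Gene lists fixed beforehand were compared with 10000 random lists of the same size and like intensity. The median deviation of 5 lists varied more between libraries than that of random lists at an adjusted share under 0.05: testis, male accessory gland and ejaculatory duct, heat shock, lipid metabolism, and germline and oogenesis. In library 3 the median deviation from the gene means was 0.61 for testis, 0.23 for accessory gland and duct, and 0.18 for heat shock genes. Lipid metabolism genes stood at 0.08 and 0.09 in libraries 1 and 2 and at -0.10 and -0.08 in libraries 3 and 4. Germline and oogenesis genes ranged from 0.07 in library 2 to -0.10 in library 4, with BicC at 172 and 131, stau at 221 and 178, and gcl at 131 and 113 in these libraries, while osk was highest in library 2 at 497 and lowest in library 3 at 363. The adjusted shares were 0.0012 for testis and for lipid metabolism, 0.0024 for accessory gland and duct, 0.006 for heat shock and 0.0168 for germline genes. Of the 5 tested accessory gland and duct genes, Mst57Da, Acp95EF and lectin-46Cb passed the filter only through library 3, so the change itself helped to select the genes behind this list's calls. In the testis list betaTub85D passed the filter only in this way. The heat shock call ended when all probe sets of a gene were averaged (0.0932), and the germline call with the filter at the 60th percentile (0.0773). Without library 3 the call ended for testis and heat shock genes (adjusted shares 0.768 and 0.532), the accessory gland and duct list had too few members past the filter to be tested, as with the filter at the 60th percentile, and the count fell to 2 lists, without library 4 it ended for germline genes (0.353), and without library 1 the count was 9.

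Within lists, the spread of single genes was above that of random lists for 5: testis, male accessory gland and duct, heat shock, digestive serine protease and lipid metabolism genes, with adjusted shares of 0.0024, 0.033, 0.033, 0.0216 and 0.0485. The median coefficient of variation was 32.2% for testis genes, 11% for accessory gland and duct genes, 10.4% for heat shock genes and 7.90% for digestive protease and for lipid metabolism genes. Among digestive proteases, Jon74E (168 ± 55.1), alphaTry (3212 ± 517) and betaTry (5893 ± 828) had the highest ratios of log2 SD to the SD expected at their intensity, and Jon44E, at 397 ± 35.4, was the middle member (SD, n = 4). When adjusted over the list alone, 7 testis, 2 accessory gland and duct, 1 heat shock, 4 digestive protease and 2 lipid metabolism genes were variable, besides 2 carbohydrate digestion genes, BomS2 and fbp. Without library 3, 0 lists passed (matched random lists; 5 had an unadjusted share under 0.05). The accessory gland and duct call ended with the floor at the 5th percentile (0.152) and with an offset (0.162), and the heat shock call when all probe sets of a gene were averaged (0.23). The lipid call ended without the filter (0.106), with the filter at the 60th percentile (0.0604), under quantile normalization (0.119) and without library 2 (0.084).

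**Figure D3:**
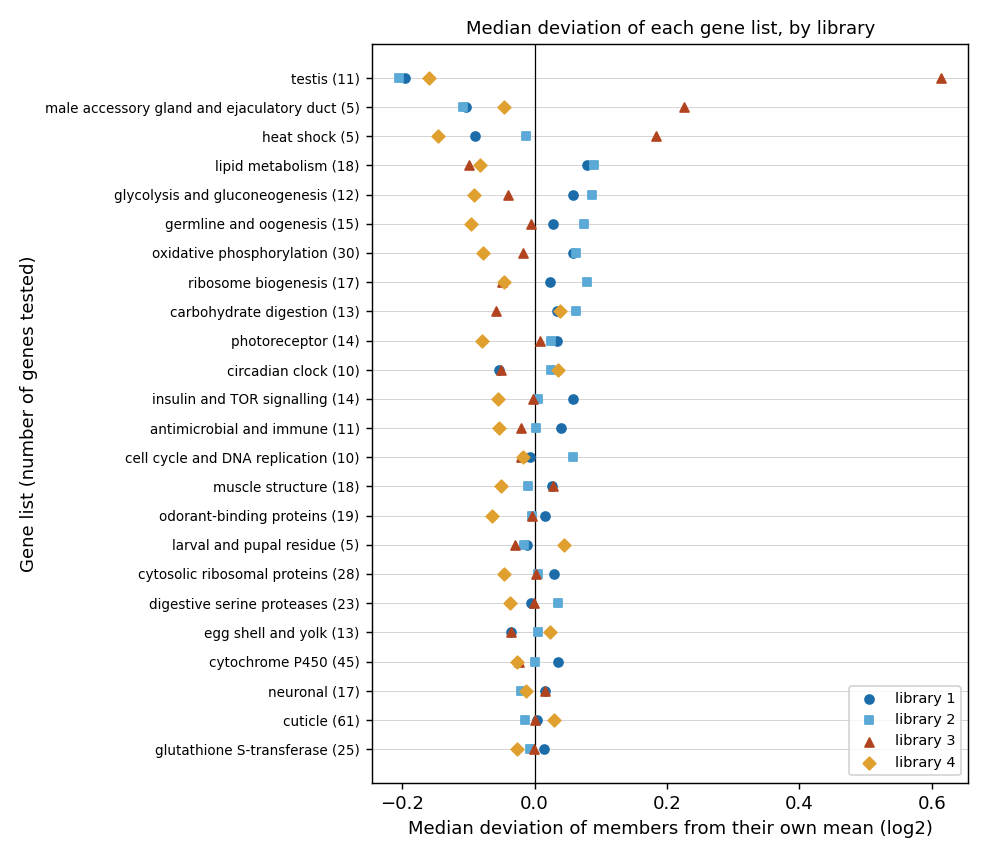
Median deviation (log2) of each gene list from its members' own means, by library; each row is 1 list with the number of tested genes in parentheses, and each symbol is 1 library. The testis list stands at 0.61 in library 3, and the lipid metabolism list at 0.08 and 0.09 in libraries 1 and 2 and at -0.10 and -0.08 in libraries 3 and 4.

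Most genes of 3 metabolic lists had lower values in libraries 3 and 4 than in libraries 1 and 2, but no single gene passed along the labelled order, and the list calls depended on the setting. The slope per labelled hour was negative for 29 of 30 oxidative phosphorylation genes, 17 of 18 lipid metabolism genes and 9 of 12 glycolysis and gluconeogenesis genes. Bright probe sets were lower in libraries 3 and 4 in general. Their median log2 difference from libraries 1 and 2 ran from 0.01 in the dimmest intensity decile to -0.07 in the brightest. The counts of negative slopes are not corrected for this. Median slopes were -0.05, -0.06 and -0.05 log2 units per labelled hour. In limma's camera test with a preset correlation these 3 lists passed as falling, with adjusted p of 0.000181 for oxidative phosphorylation, 0.00430 for lipid metabolism and 0.0289 for glycolysis, and the cuticle list passed as rising, with a median slope of 0.01 and an adjusted p of 0.0289. None of these calls held with an estimated correlation in camera: the adjusted p was 0.75 for all 4 lists, and 0 lists had an unadjusted p under 0.05. That setting can hardly call any list with so few libraries, so its result says little about these calls either way. Quantile normalization ended the call for oxidative phosphorylation (median slope -0.02, adjusted p = 0.164) and for glycolysis (-0.02, 0.192). Leaving out library 4 ended both calls in camera too (adjusted p 0.0558 and 0.0658), though the median slopes were -0.03 and -0.05. The same omission ended the cuticle call (0.718) and turned the cuticle list's median slope to -0.01. The filter at the 60th percentile ended the camera calls for glycolysis (0.352, with a median slope still at -0.05) and cuticle (0.2). The cuticle call also ended without library 2 (0.0601) and without library 3 (0.0568). The lipid list passed with the preset correlation in each of these settings, and it also moved beyond random lists. Oxidative phosphorylation and glycolysis did so only in other settings: both without library 1 (adjusted shares 0.0183 and 0.00768), and glycolysis with the mean of list members (0.02). The higher 3' to 5' ratio and the brighter hybridisation controls also set libraries 3 and 4 apart from libraries 1 and 2. Both measures fell from library 1 to library 2 and from library 3 to library 4.

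Among the genes behind these lists, apolpp, which encodes the lipoprotein of the fly's blood, had intensities of 936 and 820 in libraries 1 and 2 and of 616 and 684 in libraries 3 and 4. Lsd-1 went with 213 and 219 against 138 and 175, and the carnitine palmitoyltransferase gene whd, the middle member of the lipid list, with 421 and 420 against 351 and 394. The gluconeogenic genes fbp (123 and 117 against 82.4 and 85.6) and Pepck1 (732 and 832 against 586 and 542) had the highest ratios of log2 SD to expected SD in the sugar list, followed by Gpdh1 at 351 and 374 against 274 and 347, while Ald1, its middle member, had 4497 ± 268 (SD, n = 4). For respiratory chain genes the values were 232 and 241 against 183 and 205 for UQCR-14, 598 and 584 against 534 and 442 for ND-39, 581 and 641 against 508 and 509 for ND-75, and 504 and 491 against 510 and 440 for SdhD. In the cuticle list Cpr92F (-0.21 per labelled hour) went against the list's direction, Cpr72Eb was lowest in library 2 at 123 against 166 to 172, and Cpr72Ea and Cpr64Ac had 269 ± 45.5 and 500 ± 28.6 (SD, n = 4).

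For single genes, no trend along the labelled order passed the threshold. The smallest p for a negative slope was that of the TGF-beta pathway gene Smox, from 144 in library 1 to 82.8 in library 4 (slope -0.29 ± 0.04 log2 units per labelled hour, SE), followed by BomS2, an immune-induced peptide gene, from 140 to 77.2 (-0.26 ± 0.04). Cpr92F, the mucin gene Muc11A and Acsx3 had slopes of -0.21, -0.18 and -0.17. Positive slopes were led by Sap-r, a saposin gene, from 104 to 155 (0.18 ± 0.03), and by CG12057 (0.21), CG1924 (0.24), CG15471 (0.14) and Unc50 (0.17). All had a limma adjusted p of 0.298, and 0 probe sets passed (968 had an unadjusted p under 0.05); without library 3 the count was 321 and without library 4 it was 22. Libraries 1 and 2 set against libraries 3 and 4 gave 11 probe sets in limma, 2 higher and 9 lower in the later pair. The lower ones named apolpp, Smox, the carboxypeptidase-like gene CG12374, BomS4, CG6295, Lk6, fbp and fon, with log2 changes from -0.51 to -0.76, besides 1 unnamed probe set, and the higher ones were CG3650 (0.63) and CG12025 (0.82). The apolpp value there, -0.72, comes from another probe set than the intensities given above. When adjusted over the list alone, 4 glycolysis and gluconeogenesis genes (Hex-C, Pgi, Pepck1 and fbp), 2 immune genes (BomS2 and Rel), 2 cuticle genes (Cpr92F and TwdlR) and 1 gene each of the muscle, odorant-binding protein and glutathione S-transferase lists (TpnC73F, Obp57c and GstE12) passed along the labelled order.

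No other list passed along the labelled order in camera with these settings, although ribosome biogenesis did without the filter (adjusted p = 0.0172) and without library 1 (0.0109), cytosolic ribosomal proteins without the filter (0.0157), germline genes without library 1 (0.00115) and immune genes without library 2 (0.0448). The testis, heat shock, and accessory gland and duct lists passed without library 4 (1.12e-13, 7.73e-06 and 4.13e-08), when library 3 stands at the end of the order. All these used the preset correlation of 0.01, while the estimates over the 4 libraries were 0.641, 0.94 and 0.896 for the last 3 lists. With estimated correlations in camera, a setting that can hardly call any list, the adjusted p over the 4 libraries was 0.75 or more for every list. With the preset value and without floor and filter, the germline, accessory gland and duct, testis, ribosome biogenesis and larval and pupal residue lists passed as well (0.0193, 0.0225, 0.0374, 0.0062 and 0.00843). For heat shock, digestive protease, carbohydrate digestion, neuronal and glutathione S-transferase genes the median slope was negative while camera's direction was up. The remaining lists did not move together beyond random lists with the floor, filter and list median used, and of these the digestive proteases had a spread above them. Adjusted shares for moving together were 0.633 for the 13 egg shell and yolk genes (Yp1 the most variable; Vm34Ca, the middle member, 388 ± 20.5), 0.625 for 11 antimicrobial and immune genes (BomS2; Mtk, 266 ± 18.1), 0.175 for 13 carbohydrate digestion genes (Amy-d; LManII, 103 ± 7.22) and 0.625 for the 23 digestive proteases. They were 0.0628 for glycolysis, 0.103 for oxidative phosphorylation, 0.776 for 28 cytosolic ribosomal protein genes (RpS19b; RpL27, 4433 ± 130), 0.0840 for 17 ribosome biogenesis genes (Nnp-1; Nopp140, 315 ± 20.9) and 0.2 for 14 insulin and TOR genes (S6k; mTor, 121 ± 6.75). For 10 circadian clock genes the share was 0.407 (cry; dco, 284 ± 16.7), for 61 cuticle genes 0.625, for 18 muscle genes 0.746 (TpnC73F, 485 ± 76.7; bt, 267 ± 15.2), for 14 photoreceptor genes 0.212 (Gbeta76C, 248 ± 19.5; ninaG, 144 ± 8.02) and for 19 odorant-binding protein genes 0.437 (Obp44a; Obp18a, 184 ± 11.6). The 17 neuronal genes had 0.746 (Sh, 132 ± 13.7; brp, 189 ± 6.53), the 45 cytochrome P450 genes 0.268 (Cyp6g1, 155 ± 32.4; Cyp305a1, 138 ± 8.49), the 25 glutathione S-transferase genes 0.746 (GstE6, 235 ± 39.9; GstT3, 267 ± 14.4), the 10 cell cycle genes 0.511 (CycB, 598 ± 87.7; CycB3, 148 ± 7.84) and the 5 larval and pupal residue genes 0.745 (Lsp2, 227 ± 22.4; Sgs8, 240 ± 8.83); all errors are SD with n = 4. Ribosomal protein genes were among the steadiest, with a median coefficient of variation of 3.07%. In other settings some of these lists did move together: ribosome biogenesis without the filter (0.0044), without library 1 (0.0427), without library 4 (0.0221), with the mean of members (0.0415) and without floor and filter (0.00048), cuticle without the filter (0.0399), without floor and filter (0.0415) and under quantile normalization (0.0006), carbohydrate digestion without library 1 (0.0168) and with the mean (0.0483), and odorant-binding proteins without the filter (0.0213). High spread appeared for cytochrome P450 genes (0.0024) and glycolysis (0.03) without library 4, for glycolysis under quantile normalization (0.0341), for carbohydrate digestion without the filter (0.0446) and for odorant-binding proteins without library 1 (0.0432). The Turandot stress list had 0 members past the filter and was not tested.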

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

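All tests that weigh explanations here were chosen only after the results were seen. A library was singled out where its gap to the nearest other library was unusually large for the range of the 4 values. Chance singles out about 1 in 20, and here it was 26 of 146 values tested: 24 of 115 genes, 2 of 24 lists and 0 measures of whole libraries. Library 3 accounts for 13 of these values, library 2 for 7, library 4 for 5 and library 1 for 1. Most of the genes had been named for a large difference, so the excess over chance is partly a product of that choice.

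Male reproductive transcripts stood out in library 3, where Mst57Da had an intensity of 662 (69.0 to 74.5 in the others), Acp95EF 416 (41.5 to 45.8), Mst84Dd 478 (126 to 133) and Mst84Da 473 (187 to 192), and the testis list had a median deviation of 0.61 (-0.20 to -0.16 in the others). Stronger hybridisation or an intensity-dependent scaling of this array is argued against by matched random lists, of which a share of 0.0001, the smallest possible, rose as much as the male lists. The median rise was 1.06 over all 41 measured members without floor or filter. Many of these, such as Acp26Aa and dj, lay below the median negative control outside library 3, so that size carries little information. Only 30 of the 41 lay above the floor in library 3 itself. Over the 12 members chosen and matched by their intensity in the other 3 libraries alone, the median rise was 0.56. The highest random list there rose by 0.12, and the share was the same. As matched comparisons on the same libraries had singled the male lists out, these shares are not separate support. Whether library 3 was made wholly or mostly from males cannot be settled by egg shell and yolk genes. Their median log2 change was -0.047 (quartiles -0.13 to 0.06, 13 genes). Their mean intensities ran only from 108 (Cp19) to 388 (Vm34Ca), while single negative controls reached 133. A list with so little signal above background has limited room to fall. Male flies or male RNA in the pool of library 3 is a candidate explanation that stays open, because the labels give no sex: the 85.4% of the 41 measured male genes that were highest there, and 26 of the 32 not called higher, restate the pattern and do not test its source.

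Genes of lipid metabolism, oxidative phosphorylation and glycolysis were lower in libraries 3 and 4 than in libraries 1 and 2, with median log2 differences of -0.16, -0.11 and -0.13. With an estimated correlation in camera the adjusted p over the labelled hour was 0.75 for each, but that setting can hardly call a list with so few libraries. Under quantile normalization the calls for oxidative phosphorylation and glycolysis ended. Intensity-dependent scaling is argued against for the lipid list, since a share of 0.0002 of matched random lists fell as much, and stays open for oxidative phosphorylation (0.0463) and glycolysis (0.0187). For the lipid list this repeats the matched comparison that had singled it out on the same libraries (share 0.0001), so it is not separate support. Loss of 5' signal stays open, since the 3' to 5' log2 ratio of control transcripts was higher by 0.32 in libraries 3 and 4 and probe positions were not analysed here. A change along the labelled order cannot be told apart from these: 1 of the 3 ways to halve the 4 libraries, the labelled one, gave a shift as large (-0.12 against -0.01 and 0.02), and 3 ways are too few to exclude chance. No biological explanation was tested, as the samples form a single group.

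Library 2 was singled out by lower single probe sets: CG14642 at 133 (285 to 324 in the others), CG2246 at 175 (335 to 337) and CG7745 at 66.2 (115 to 120). A fall of all transcripts of sdt and scaf6, also lower there, is argued against by the 8 other probe sets of these genes, with a median log2 change of -0.017 (range -0.16 to 0.26). A fault in single probe sets on this array stays open, because 2 of the 8 lower genes have another probe set. No biological explanation was tested.

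In library 3, further values apart from the others were those of CG12699 at 190 (69.0 to 81.5), CG4836 at 316 (126 to 142), CG2127 at 287 (128 to 135), CR17567 at 252 (110 to 126), Hsp26 at 286 (135 to 149), CG1394 at 175 (85.7 to 90.1), Obp44a at 419 (282 to 292) and ap at 119 (188 to 198). In library 2 they were Dhc36C at 192 (109 to 113), CG16762 at 188 (132 to 137), Cpr72Eb at 123 (166 to 172) and the cell cycle and DNA replication list at a median deviation of 0.0587 (-0.0207 to -0.00718). In library 1, PMP34 stood at 126 (193 to 204). In library 4 they were CG34458 at 373 (239 to 258), CG7296 at 286 (201 to 208), CG13047 at 227 (166 to 171), CG4328 at 71.3 (127 to 141) and unc-13 at 144 (186 to 194).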

How the results depend on the processing

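The alternative without floor and filter together was chosen only after the data were seen; the others were planned. The floor at the 5th percentile left each count within 1.5 times its first value but ended the high-spread call of the accessory gland and duct list (adjusted share 0.033 to 0.152), and the median correlation stayed between 0.984 and 0.989 with any replicate left out.

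Without the filter the median absolute log2 difference was 0.0662, variable probe sets 0 (limma-based test; 3120 at an unadjusted p under 0.05), calls for libraries 1 to 4 52, 30, 129 (128 higher) and 106, and lists moving together 8. In 50 of the 52, 29 of the 30, 113 of the 129 and 102 of the 106 calls the other 3 libraries lay at the floor, where 2392 probe sets have no spread by construction. With an offset in place of the floor the median difference was 0.065, and library 4 had 0 calls.

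With the filter at the 60th percentile, where fewer genes are tested, there were 12 variable probe sets, all among the 23, and 1, 5, 24 and 0 calls for libraries 1 to 4, the 24 all among the 59. Lists fell to 3 moving together, 3 of high spread and 2 over the labelled hour, and the accessory gland and duct list had too few members to be tested, as without replicate 3. Without floor and filter there were 60 variable probe sets, with all 23 among them, 142 calls for library 3, with all 59 among them, 0 for library 4, and 9 lists over the labelled hour.

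Quantile normalization gave 0 calls for library 4 and 2 lists over the labelled hour; median centring gave 0 calls for library 4. A prior that is not robust gave 10 variable probe sets, 5 calls for library 2 and 0 for library 4. Over the 6 settings with 0 calls for library 4 in limma, 523 to 994 probe sets had an unadjusted p under 0.05. The first against the last 2 labelled hours gave 11 probe sets, the mean of list members 8 lists moving together, and the estimated correlation 0 lists over the labelled hour (camera; 0 at an unadjusted p under 0.05). The cause was not tested for these.

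With each replicate left out in turn, which leaves fewer samples and 1 residual degree of freedom for a lone library, assumed to vary like the others, variable probe sets ranged from 0 to 57 and labelled-hour trends from 0 to 321. Calls ranged from 5 to 18 for library 2, 52 to 504 for library 3 and 0 to 503 for library 4, lists moving together from 2 to 9 and lists of high spread from 0 to 7. The lowest counts of variable probe sets and of both kinds of list came without replicate 3. The highest counts for libraries 3 and 4 took their spread from libraries 1 and 2 alone, the closest pair, and can be inflated.

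Genes called for 1 library and lists called over the labelled hour reversed in no setting by their test, although the median slope of the cuticle list changed sign without replicate 4. The tests for variable genes, lists moving together and lists of high spread have no direction, so a reversal could not occur there. Averaging all probe sets of a gene ended both calls for heat shock genes (adjusted shares 0.0932 and 0.23). Of values for single lists, 821 kept their side of the threshold, 32 came to pass and 29 ceased to. For genes named as variable the numbers were 179, 15 and 52, for those named over the labelled hour 109, 12 and 0, and for those named for 1 library 230, 8 and 15. The median signal over background is limited by negative controls at 46.1 to 48.7 against a median intensity of 112.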

Other observations

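The test of other orders of the 4 libraries was chosen only after the result was seen. The labelled order gave 0 probe sets with a trend in limma (968 at an unadjusted p under 0.05), and the highest count among the other orders was 3. Since the labelled order gave 0, each of the 12 orders gives at least as many by construction, so this comparison says nothing about chance.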
